A study of Zea mays with 24 samples.

How the data were processed

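Gene expression in the maize (Zea mays) root tip was measured by RNA sequencing in 24 libraries, 3 for each of 8 groups, from plants aged 7 days after germination and grown at 26 °C with 12 h of light and 12 h of dark. Per the labels, epidermis, cortex and stele were sorted by flow cytometry from wild-type B73 protoplasts stained for 15 min with fluorescent dyes. Endodermis was sorted from a line with a ZmSCR::RFP reporter and the quiescent center from a line with a ZmWOX5::RFP reporter, both in a B73/Hi-II background. The remaining groups, all wild-type B73, were unsorted protoplasts without root cap, intact root tips without cap, and dissected root cap. Sorting method and genetic background are therefore confounded with tissue for the endodermis and the quiescent center. RNA was extracted with a micro-scale column kit and libraries were made with an amplifying kit for small amounts of RNA, per the labels' protocols.

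The titles number the replicates 1 to 3. The descriptions of the third epidermis, stele and cortex libraries carry the number 2, and the title's number was used. The labels do not say whether replicates came from separate plants or sorts, so the p-values measure only the spread between these samples, which may be technical. No pair of libraries of a group held the same reads, and each library was counted as a replicate. Whether libraries of a group were made from shared RNA cannot be read from these values.

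The submitters' processing notes name Trimmomatic, kallisto 0.43 and DESeq2. The genome build and annotation were not given in the sources used here. The deposited table holds normalized values per gene, a signal in the sense of gene counts divided by a size factor per library, for 39510 gene identifiers, and 8 columns of group averages by the authors were not used. Within each library the values were whole multiples of the value of 1 read, which ranged from 0.604 to 1.49. In every library 100.0% of the values above 0 lay within 0.01 of a whole number of reads, so read numbers per gene were recovered. In 3 libraries the step itself lay within 0.01 of 1, where such a test is weak. Since kallisto estimates counts, the recovered reads are estimated counts that appear to have been rounded, and genes that share sequence with a near-identical copy carry uncertain values.

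Recovered reads ranged from 21978670 to 50289026 per library, with a median of 31133613.0. A gene listed at 0 in a library may hold up to 3 reads by counting error, worth 1.81 to 4.46 normalized units depending on the library. This floor covers counting error only, since amplified reads are not independent molecules. Folds given as at least a value hold against this floor only.

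Genes were tested when their value was at least 10 in at least 3 libraries, which kept 25555 genes. The values were transformed as log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3, using a mean per group over all 24 libraries and a trended prior variance. The p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison. A gene was called when its adjusted p was below 0.05 and its log2 fold change was at least 1 in size. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. For genes at 0 in every library of a group, the fold is a lower bound from geometric means of the values against the floor of 3 reads per library. Each of 5 sorted tissues was compared with the mean of the other 4, cortex with endodermis, unsorted protoplasts with intact tips, and root cap with intact tips. These comparisons, tests, gene lists and most alternatives were fixed before the data were examined. Specific genes were those called higher than in each of the other 4 sorted tissues.

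None of the identifiers matched the supplied reference table of 49888 genes (0 of 39510), and the deposited table does not pair identifiers with names. The fixed gene lists and the reporter genes SCR and WOX5 were therefore not analysed here. The planned rule for named genes asked for genes with a name. That clause was dropped once the mismatch was seen, and per comparison up to 2 identifiers that rose and 2 that fell are given. They are those with the largest change among called genes with a mean of at least 100 in the higher group and with every library beyond every library of the groups compared.

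A set score is the mean log2(value + 1) of a set of genes in a library minus the mean over all tested genes in that library. In the groups whose comparison chose a set, its high or low score follows from that choice and is descriptive only. Sets called in the protoplast and root cap comparisons were scored in the 15 sorted libraries with exact two-sided permutation tests over 455 splits, adjusted over 20 tests. The sorted libraries entered the filter and the variance behind these sets, so the sets were also chosen by a filter and a fit on the 6 libraries compared alone. These set tests were added after the data were seen.

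The pipeline was tested on simulated counts with 200 changed genes per comparison. Median estimated changes lay close to those simulated. For cortex against endodermis, over 25106 genes, 17.9% of genes changed by 4-fold and 50% of genes changed by 16-fold were recovered, with 3 false calls. For endodermis against the other 4 sorted tissues, over 25100 genes, 32.8% and 72.7% were recovered, with 7 false calls. Of genes changed by 2-fold, the size of the calling threshold, 0% and 7.5% were recovered in these comparisons. A first version of this test required a higher recovery at 16-fold than was reached. It was replaced by a requirement on the estimated change and on false calls. What limited the recovery was not tested.

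Alternatives were TMM and quantile normalization, pseudocounts of 0.5 and 10, other filters, a replicate block, weights per group, fits of the compared groups alone, other references, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Leaving out the quiescent center libraries was added after the data were seen, as were the comparisons of epidermis with cortex, cortex with stele and endodermis with stele. Other calculations used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were made with matplotlib 3.10.9.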

Results

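The data describe 5 tissues sorted from the maize root tip, together with unsorted protoplasts, intact root tips without cap and dissected root cap, with 3 libraries in each group. Sequencing depth was highest in the endodermis, with 45329654 ± 4799558 recovered reads (SD, n = 3), and lowest in the root cap, with 26157696 ± 3528604 recovered reads (SD, n = 3). The number of genes with a normalized value of at least 10 was highest in the stele, at 22232 ± 178 (SD, n = 3), and lowest in the quiescent center, at 19373 ± 747 (SD, n = 3). The quiescent center is the small group of slowly dividing cells at the center of the root stem cell niche.

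Among sorted tissues, epidermis and cortex, and endodermis and stele, were the most alike, and the quiescent center stood apart. Across genes, the mean Spearman correlation between epidermis and cortex libraries was 0.917, that between endodermis and stele was 0.913, and that between cortex and stele was 0.883. Cortex and endodermis, which together form the ground tissue, had a mean correlation of 0.823. Quiescent center libraries had a mean correlation of 0.815 with each other and of 0.694 to 0.731 with the other groups. Among sorted tissues, the unsorted protoplasts were closest to the stele (0.898) and the cortex (0.877). Genes are not independent replicates, and these correlations describe the libraries.

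**Figure D1:**
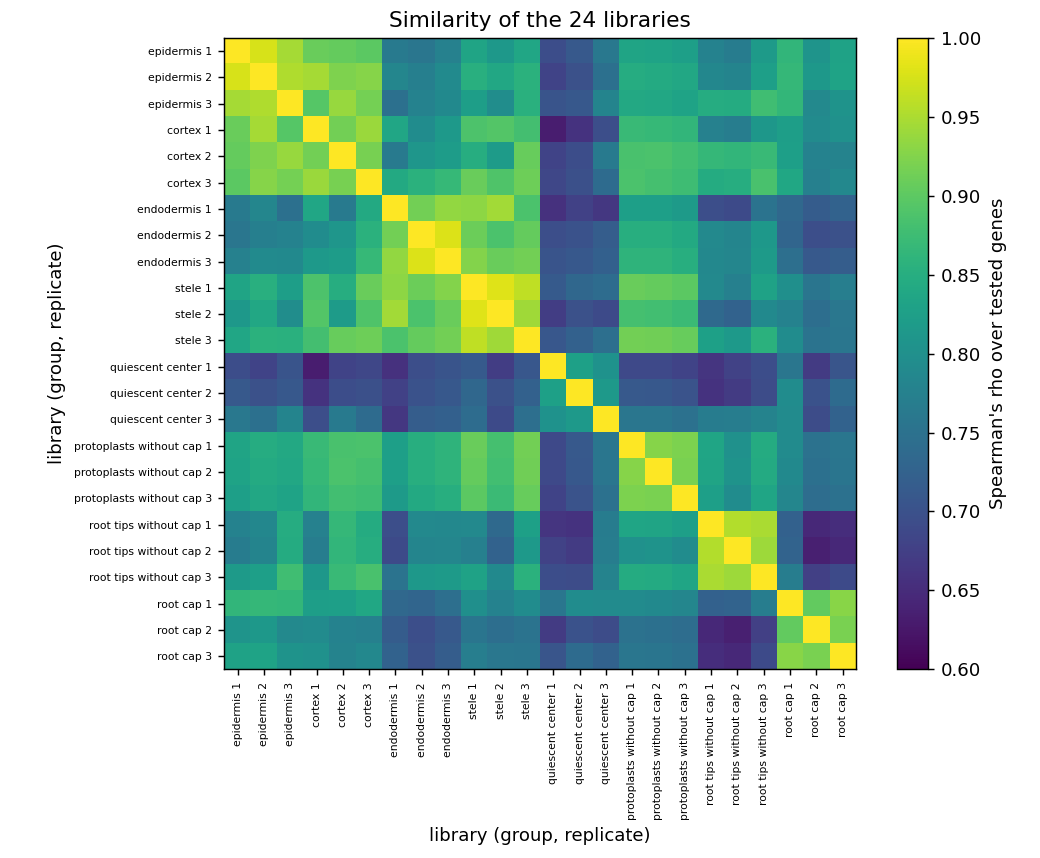
Spearman correlation of log2(value + 1) over the 25555 tested genes between each pair of the 24 libraries, named by group and replicate on both axes, with color giving rho. Epidermis and cortex (mean 0.917) and endodermis and stele (mean 0.913) form pairs, and the quiescent center libraries are low against the other groups (mean 0.694 to 0.731).

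**Figure D2:**
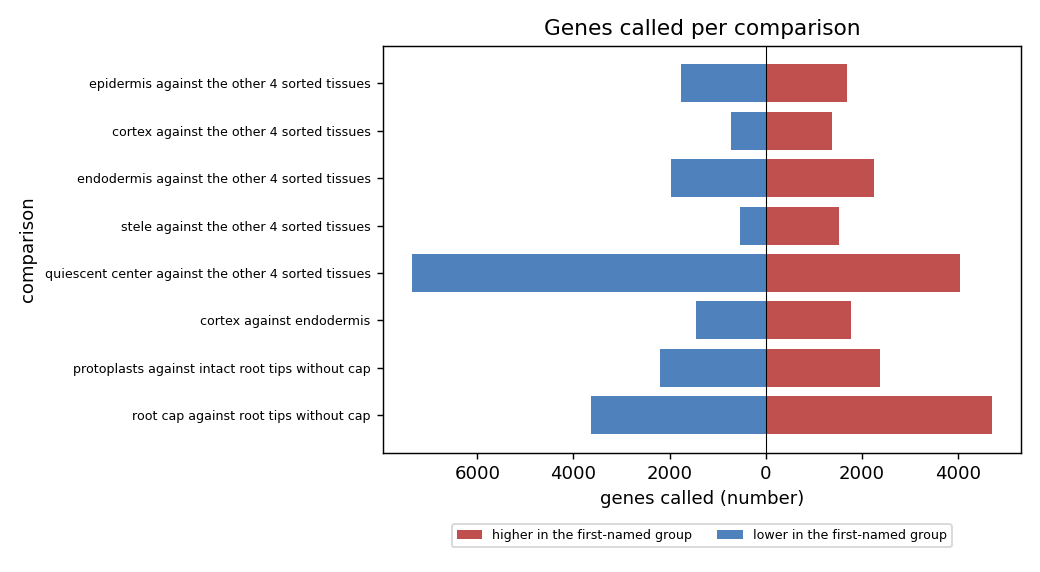
Number of genes called in each of the 8 comparisons by limma, with genes higher in the first-named group to the right of 0 and genes lower to the left. The quiescent center had the most, with 4039 higher and 7353 lower.

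Epidermis, the outer layer of the root, had 1691 genes higher and 1771 lower than the mean of the other 4 sorted tissues. Zm00001d013945 reached 30813 ± 9830 in the epidermis (SD, n = 3), against 2813 ± 1282 in the cortex and 0 in all quiescent center libraries. Zm00001d032691 also rose, to 4578 ± 3224 (SD, n = 3). Zm00001d013699 and Zm00001d046332 fell by 8.31 (SE 0.65) and fell by 7.71 (SE 0.55) on the log2 scale. Genes higher in the epidermis had a set score of 2.27 ± 0.11 there, 1.16 ± 0.15 in the cortex and −0.93 ± 0.19 in the stele (SD, n = 3). Specific to the epidermis against each other sorted tissue were 26 genes. Their set score was 2.38 ± 0.39 in the epidermis and 0.10 ± 0.19 in the root cap (SD, n = 3). It was −1.41 ± 0.33 in intact tips and −1.81 ± 0.06 in unsorted protoplasts, both without cap (SD, n = 3). The titles name removal of the cap only for these unsorted protoplasts and intact tips. Cap cells among the sorted tissues were therefore not excluded. Without epidermis replicate 1 the total fell from 3462 to 2050, and weights per group raised it to 5696. Against the other dye-sorted tissues 808 genes were higher and 1477 lower. With edgeR and TMM factors the split was 2088 higher and 1124 lower.

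The cortex, the layers of ground tissue beneath the epidermis, had 1381 genes higher and 734 lower than the mean of the other 4 tissues. Zm00001d036072 reached 11858 ± 2780 in the cortex and 1742 ± 561 in the epidermis (SD, n = 3), and Zm00001d043731 reached 4091 ± 918 (SD, n = 3). Zm00001d042932 and Zm00001d034062 fell by 3.79 (SE 0.66) and fell by 2.52 (SE 0.40) on the log2 scale. Genes higher in the cortex were nearly as high in the epidermis, with set scores of 2.53 ± 0.25 and 2.10 ± 0.21 (SD, n = 3), and 1 gene was specific to the cortex. Epidermis and cortex compared directly differed in 260 genes. This count was 3, all higher in the epidermis, when these groups were fitted alone, 674 without the quiescent center, 38 and 164 without epidermis replicates 1 and 3, and 150 and 600 without cortex replicates 1 and 2. Cortex and stele differed in 1155 genes, and in 513, 401 and 427 without cortex replicate 1, stele replicate 1 and stele replicate 2. The total of 2115 depended on cortex replicate 1, without which it was 773, and it was 1301 without the quiescent center and 38 against the other 2 dye-sorted tissues. Quantile normalization gave 1364 higher and 1124 lower, and edgeR gave 1805 and 374.

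The endodermis, the innermost layer of the ground tissue, had 2241 genes higher and 1968 lower than the mean of the other 4 tissues. Zm00001d048311 reached 8248 ± 1251 there (SD, n = 3), against 660 ± 230 in the stele and 0 in all quiescent center libraries. Zm00001d023477 reached 6768 ± 3904 (SD, n = 3). Zm00001d004725 and Zm00001d004729 fell by 9.61 (SE 0.55) and fell by 8.89 (SE 0.82) on the log2 scale and were high in the epidermis, at 24458 ± 3674 and 33314 ± 2704 (SD, n = 3). Both were also high in the dissected root cap, at 13715 ± 4363 and 15679 ± 4144 (SD, n = 3). In intact tips without cap, which hold epidermis, they were at 132 ± 36 and 252 ± 102 (SD, n = 3). The 153 genes specific to the endodermis had a set score of 0.65 ± 0.47 there and of −3.31 ± 0.11 in intact root tips (SD, n = 3), a tissue that holds endodermis. Genes specific to the epidermis and to the stele also scored lower in intact tips, at −1.41 ± 0.33 beside 2.38 ± 0.39 in the epidermis and −2.02 ± 0.27 beside 0.97 ± 0.30 in the stele (SD, n = 3). The endodermis came from a reporter line in another background than the dye-sorted tissues, so tissue and line cannot be told apart. Without endodermis replicate 2 the total fell from 4209 to 2743, and edgeR gave a split of 2750 higher and 1513 lower.

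The stele, the central cylinder with the vascular tissue, had 1524 genes higher and 546 lower than the mean of the other 4 tissues. Zm00001d035689 reached 6413 ± 1308 and Zm00001d043477 reached 2821 ± 427 in the stele (SD, n = 3). Zm00001d048138 and Zm00001d035664 fell by 2.50 (SE 0.30) and fell by 2.48 (SE 0.50) on the log2 scale. Genes higher in the stele were also high in the endodermis, with a set score of 1.12 ± 0.13 beside 1.72 ± 0.11 in the stele (SD, n = 3), and 30 genes were specific to the stele. Endodermis and stele compared directly differed in 727 genes, in 308 and 364 without endodermis replicates 2 and 3, and in 440, 484 and 390 without stele replicates 1, 2 and 3. Without stele replicate 1, 2 or 3 the total of 2070 was 1002, 771 or 1320. It was 4202 with weights per group, 1172 against unsorted protoplasts and 3178 against the other dye-sorted tissues, and quantile normalization gave 1351 higher and 1073 lower.

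In the quiescent center 4039 genes were higher and 7353 lower than the mean of the other 4 tissues, the largest number of the 8 comparisons except with weights per group. Genes at 30 to 100 in the other libraries of the group were at 0 in 1 quiescent center library in 20.6% of cases. The share was at most 0.70% in the other sorted tissues. Genes with a mean of 30 to 100 in the quiescent center had a median SD of 3.53 on the log2 scale. Zm00001d014016 reached 5125 ± 1337 and Zm00001d028471 reached 3553 ± 2022 (SD, n = 3). Zm00001d051362 and Zm00001d007700 were at 0 in all 3 quiescent center libraries. Against a floor of 3 reads per library, they were at least 7142-fold and 3386-fold below the geometric mean of the other 4 tissues. Against the endodermis, the lowest of these tissues, they were at least 1686-fold and 94.4-fold lower. Given the zeros in single libraries, these folds are not bounds against such losses. Specific to the quiescent center were 1339 genes, a count that rests on 1 spread per gene for all groups and was not recomputed with weights per group. Genes lower in protoplasts than in intact tips scored 0.40 in the quiescent center and −0.51 in the other sorted tissues (exact permutation p = 0.0022, the smallest that 455 splits can give, adjusted p = 0.044), above the other tissues' mean by 0.91. With the set chosen from protoplasts and intact tips alone, 1962 genes of which 1371 were shared, the difference was 0.35 (exact permutation p = 0.130) and no longer past the threshold. The split between higher and lower depended on the processing. TMM factors kept it near the main split, with 3856 higher and 7583 lower. Quantile normalization gave 5690 higher and 5199 lower and moved the median log2 change from −0.49 to 0.05. The split was 4496 and 6395 with pseudocount 10, 4833 and 5643 with edgeR, and 5253 and 6041 with DESeq2. Weights per group lowered the total from 11392 to 4940, with 1436 higher and 3504 lower. That total lay below the root cap (8934), epidermis (5696), endodermis (5558) and protoplast (5220) comparisons.

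Cortex and endodermis are both ground tissue, and their comparison asks how the layers differ. There were 1778 genes higher in the cortex and 1460 higher in the endodermis. On recovered reads, edgeR gave 1469 and 924, and DESeq2 gave 2225 and 1510. Zm00001d037041 and Zm00001d036072 were 12.42 (SE 0.54) and 12.04 (SE 0.96) log2 units higher in the cortex. Zm00001d045905 fell by 9.06 on the log2 scale (limma adjusted p = 3.28e-06) and Zm00001d038177 fell by 8.73 (limma adjusted p = 7.96e-04). Across layers, 399 genes were higher in both epidermis and cortex than in both endodermis and stele, and 332 genes were higher in both inner tissues. The cortex was sorted by dye and the endodermis by reporter, so sorting method, background and tissue cannot be told apart.

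Protoplasts are cells freed of their walls, and they were compared with intact tips. A change in expression on isolation and a change in the mix of cells cannot be told apart in this comparison. Genes higher in the stele scored 0.81 ± 0.03 in protoplasts and −0.11 ± 0.12 in intact tips (SD, n = 3). Genes higher in the epidermis went the other way, at 0.01 ± 0.04 and 0.31 ± 0.23 (SD, n = 3). There were 2370 genes higher and 2192 lower in protoplasts. Zm00001d031796 reached 7208 ± 233 and Zm00001d006948 reached 15491 ± 136 in protoplasts (SD, n = 3), against 0.331 ± 0.574 and 3.48 ± 5.19 in intact tips. Both were also high in the dissected root cap, at 12959 ± 5172 and 44303 ± 31173 (SD, n = 3). Zm00001d014496 and Zm00001d008444 were at 0 in all protoplast libraries and, against the floor for counting error, at least 278-fold and 85.99-fold lower. In protoplasts, genes at 100 to 300 in the other libraries were at 0 in a single library in 2.24% of cases. These folds are therefore not bounds against such losses. The genes higher in protoplasts scored 2.46 ± 0.08 in protoplasts, −1.39 ± 0.49 in intact tips, 2.14 ± 0.42 in the root cap and between 1.26 and 2.11 in the sorted tissues. No sorted tissue passed the adjusted permutation test for this set, with the smallest adjusted p at 0.209 in the stele (exact test, higher by 0.63). Without root tips without cap replicate 2 the total of 4562 was 2942.

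The root cap covers the tip of the root, and it was compared with tips from which it had been removed. There were 4693 genes higher and 3628 lower in the cap. Zm00001d019364 and Zm00001d038740 were 15.87 (SE 1.65) and 14.62 (SE 1.04) log2 units higher in the cap. Zm00001d038598 fell by 13.54 (SE 1.13) on the log2 scale. Zm00001d052835 was at 0 in all root cap libraries and, against the floor for counting error, at least 2858-fold lower. In the root cap, genes at 30 to 100 in the other libraries were at 0 in a single library in 9.55% of cases. This fold is therefore not a bound against such losses. Genes higher in the cap scored 1.94 ± 0.56 in the cap, −2.03 ± 0.35 in intact tips and 0.02 ± 0.02 in unsorted protoplasts (SD, n = 3). They had close scores in the 5 sorted tissues, from −0.15 to 0.12, and no tissue passed the exact permutation test, with the smallest p at 0.290 in the endodermis. Genes lower in the cap scored 0.08 in the quiescent center and 0.95 in the other sorted tissues (exact permutation p = 0.0066, adjusted p = 0.066), a difference that did not pass the adjustment. Quantile normalization reversed the balance to 4104 higher and 5053 lower.

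**Figure D3:**
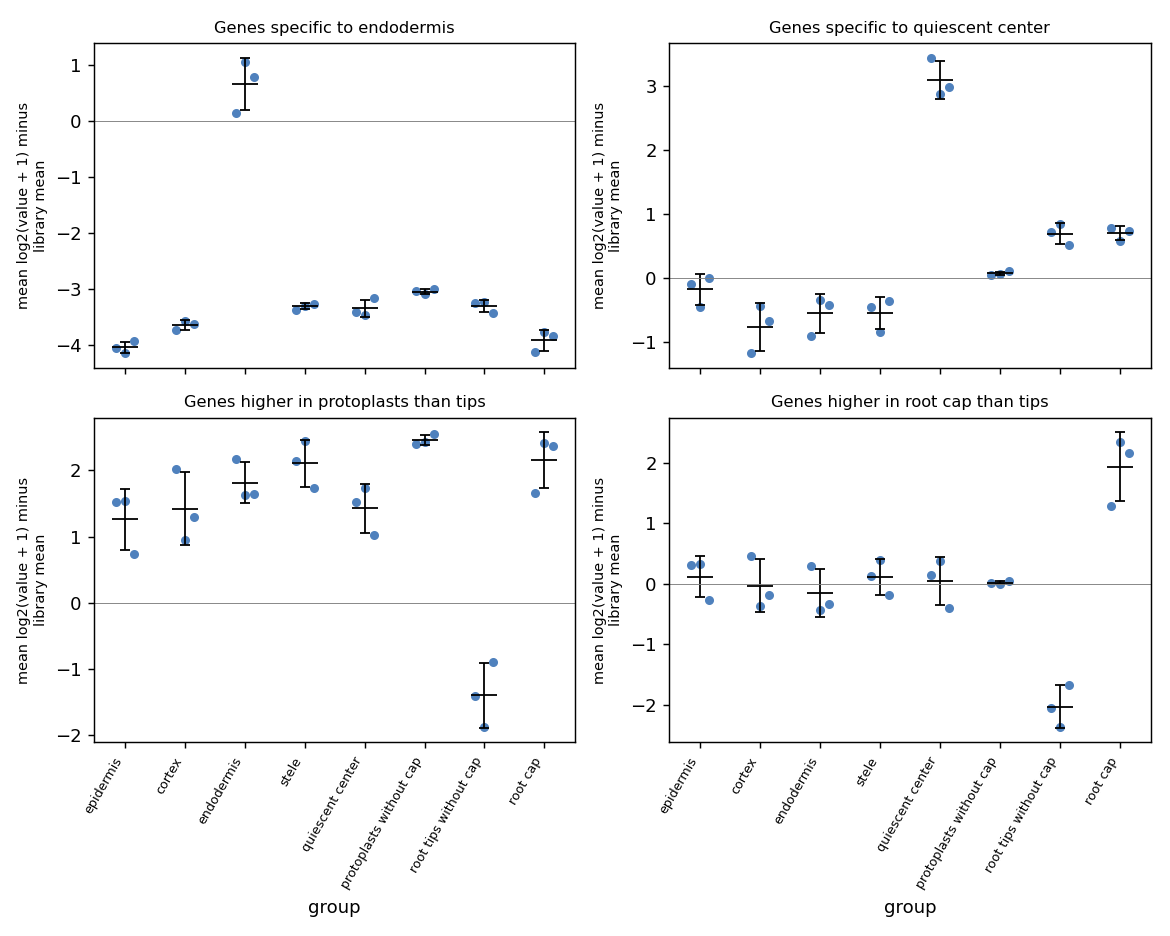
Set score per library, the mean log2(value + 1) of a gene set minus the mean of all tested genes, for 4 gene sets in the 8 groups, with points for libraries and bars for the mean and SD of 3 libraries. Genes higher in protoplasts than in intact tips score 2.14 in the root cap and −1.39 in intact tips.

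**Figure D4:**
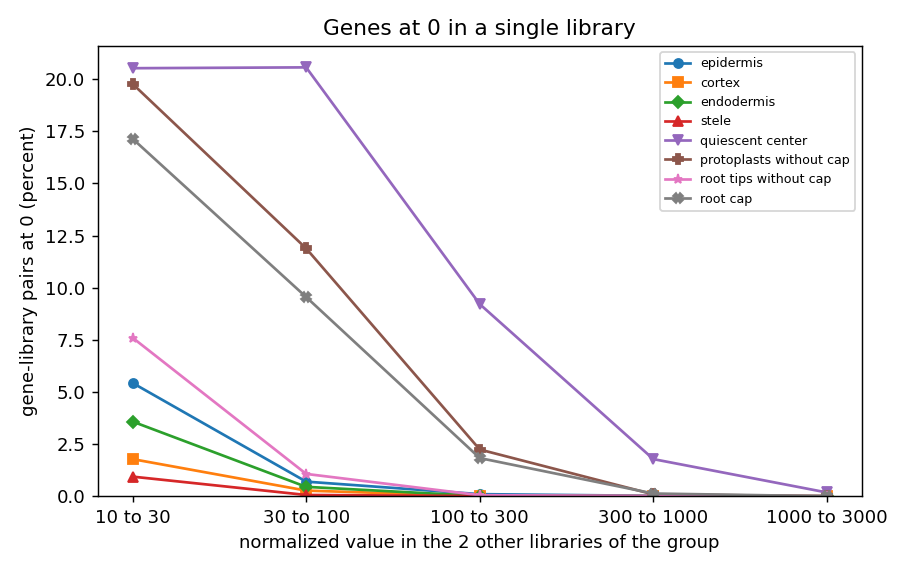
Percent of gene-library pairs at 0 in 1 library, by the normalized value in the 2 other libraries of the group, for the 8 groups. At 30 to 100 the share is 20.6% in the quiescent center, 11.9% in unsorted protoplasts and 9.55% in the root cap, and at most 1.07% in the other groups.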

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

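All comparisons of epidermis with cortex, cortex with stele and endodermis with stele, the fits without the quiescent center and the set scores were chosen after seeing the data. Of 266 recomputed counts, 220 stayed within 1.5 times the main count and 46 did not. Of 834 recomputed values for single genes, 825 kept direction and threshold and 9 were no longer past the threshold, all of them against the unsorted protoplasts or the other dye-sorted tissues. Of 380 recomputed set scores, 370 kept their side of an unadjusted p of 0.05, 9 lost it and 1 gained it. Of those that lost it, 8 were in the stele with 1 library left out, and the other was that of genes lower in protoplasts in the quiescent center, 0.91 in the report and 0.35 with the set chosen from the compared groups alone. No single gene or set score past its threshold changed direction. Except where noted, the cause was not tested.

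With weights per group the counts were 5696 (epidermis), 4202 (stele), 4940 (quiescent center), 766 (epidermis against cortex), 2213 (cortex against stele) and 2763 (endodermis against stele). Genes beyond each of the other 4 tissues, a stricter condition by construction, numbered 123, 7, 307, 40 and 4686 for epidermis, cortex, endodermis, stele and quiescent center. Unlike the specific genes, they may be higher or lower, and they passed an adjusted p below 0.05 with no fold threshold. Against the other dye-sorted tissues there were 2285, 38 and 3178 for epidermis, cortex and stele, and the stele had 1172 against unsorted protoplasts. Without the quiescent center there were 1301 for the cortex, 674 for epidermis against cortex, 2085 for cortex against stele and 1390 for endodermis against stele. With pseudocount 10 there were 421 for epidermis against cortex and 1852 for cortex against stele. Fitting the compared groups alone left 3 for epidermis against cortex, all higher in the epidermis, and 1613 for endodermis against stele. On recovered reads, edgeR gave 626 for cortex against stele and 381 for endodermis against stele, and DESeq2 gave 1116 for epidermis against cortex and 1242 for endodermis against stele.

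With each library left out in turn the counts ranged from 2050 to 4268 (epidermis), 773 to 2875 (cortex), 2743 to 4762 (endodermis), 771 to 2571 (stele), 10255 to 11399 (quiescent center), 2195 to 3218 (cortex against endodermis), 2942 to 4081 (protoplasts) and 6884 to 8305 (root cap). They ranged from 38 to 600 for epidermis against cortex, 401 to 1223 for cortex against stele and 308 to 926 for endodermis against stele. The extremes for epidermis against cortex were without epidermis replicate 1 (38) and without cortex replicate 2 (600).

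Deviations of same-numbered libraries had a mean correlation of −0.0024 over 84 pairs, 14 of them over 0.1, and 7 of 24 libraries correlated best with their own number. With a replicate block the counts were 3387, 1992, 4098, 1954 and 11299 for the 5 tissues, 3098 for cortex against endodermis, 4468 for protoplasts and 8214 for the root cap, and the block moved no count by over 1.5 times.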

Other observations

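The tests of gene sets, of zeros in single libraries, of the shared axis and of the root cap pattern were chosen after the result was seen. Counts over other splits of the libraries were planned before for the comparisons fixed in advance. The comparisons of epidermis with cortex, cortex with stele and endodermis with stele were added later, and so were their splits.

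Genes seen in a single group were few. A value of at least 10 in all 3 libraries of a group and at most 3 reads in every other library was found for 25 genes in the endodermis, 20 in the root cap, 9 in the quiescent center and 1 in the stele, and for 0 in the remaining groups. In the opposite direction, 32 genes were at 3 reads or fewer in the quiescent center and at least 50 in every other library, as were 6 in intact root tips, 4 in unsorted protoplasts, 1 in the endodermis, 1 in the root cap and 0 in the other groups. Zeros in single libraries were also most frequent in the quiescent center. The endodermis libraries were the deepest, at 45329654 ± 4799558 recovered reads (SD, n = 3), while the limit of 3 reads was the same for all libraries. Endodermis and quiescent center also came from reporter lines in another background. Depth and line therefore cannot be told apart from tissue in the endodermis count, nor line from tissue in the quiescent center counts.

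Genes were counted over random splits of the 15 sorted libraries, 100 for each tissue with the real one included. The other splits mix tissues within a group, which widens the spread within groups, and their median was 0 genes called for each tissue. Few calls are built into such splits, so they do not exclude chance. For the epidermis 2 splits gave as many genes as the real 3462, the highest other calling 3482. For the cortex it was 2 splits, real 2115 and highest other 2886, and for the stele 2 splits, real 2070 and highest other 2198. For the endodermis it was 1 split, real 4209 and highest other 3096, and for the quiescent center 1 split, real 11392 and highest other 2265. The comparisons of 3 against 3 allow 10 splits, too few for a share under 0.05, and in each 1 split, the real one, was the highest. Real and highest other values were 3238 and 16 for cortex against endodermis, 4562 and 10 for protoplasts, and 8321 and 12 for root cap. They were 260 and 2 for epidermis against cortex, 1155 and 225 for cortex against stele, and 727 and 3 for endodermis against stele.

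Genes with normalized values of 30 to 100 in the other libraries of a group were at 0 in the remaining library in 20.6% of cases in the quiescent center, 11.9% in unsorted protoplasts and 9.55% in the root cap, against 0.06% to 1.07% in the other groups. Sequencing depth as the source is argued against for the quiescent center and the unsorted protoplasts. Stele libraries thinned to 24991925 reads, the depth of the shallowest quiescent center library, had 0.08% of zeros. The shallowest root cap library held 23121418 reads, below that depth. The shallowest cortex library held fewer still, 21978670, and the cortex had 0.27% of zeros. Few starting RNA molecules are a candidate explanation for the unsorted protoplasts, since the share fell to 0.09% for genes at 300 to 1000, and the median SD of log2 values above 10000 was 0.06 there, below 0.23 in intact tips. In the quiescent center and the root cap the share fell to 1.78% and 0.13%, but that SD was 0.48 and 0.43, above intact tips, so few molecules and another kind of spread at low values cannot be told apart there. A spread equally wide at all levels is argued against, since the cortex, with an SD of 0.56 above 10000, had 0.27% of zeros at 30 to 100. The small spread in protoplasts may also mean that the libraries share RNA, which was not tested. The quiescent center is also a biologically distinct tissue, and a biological explanation stays open as untested.

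Deviations of libraries from their group means shared an axis across groups, which held 17.7% of the variance within groups when the quiescent center was left out. Whether protoplast isolation contributes cannot be told apart, since of the groups never made into protoplasts the intact root tips spanned 0.93 of the median range of the 4 layers and the root cap 0.29, with 3 libraries each. Across genes the axis had r = 0.34 with the change from intact tips to protoplasts and r = 0.39 with that to the root cap. Whether depth contributes cannot be told apart, since the axis score and recovered reads, both within groups, had r = 0.24 over 21 libraries (permutation p = 0.467; 95% interval −0.15 to 0.66), rho = 0.27 (permutation p = 0.341), and r = 0.26 without the 2 farthest libraries. Replicate number also cannot be excluded, with a largest mean score of 0.13 for a number (permutation p = 0.245). No batch is given in the labels, and no biological explanation was tested.

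Genes higher in protoplasts than in intact tips were also high in the root cap, which was dissected and not made into protoplasts. Isolation as the sole condition with high levels is argued against, since over these 2370 genes the median log2 difference of root cap minus protoplasts was 0.27 (quartiles −0.71 and 1.24), while that of intact tips minus protoplasts was −3.41. Root cap cells with the profile of the dissected cap are argued against too as the whole source. The 510 genes higher in the cap than in each sorted tissue lay at a median of −5.62 in protoplasts minus cap (upper quartile −3.39). The 257 of them with a mean of at least 1000 in the cap lay at −4.25 (upper quartile −2.51). Their choice as lower in sorted protoplasts than in the cap largely set the sign of this difference. Only its size bears on the question, and cap cells low in these genes are not excluded. The gene set was redefined after values were seen, first by leaving the intact tips out of its choice and then by keeping abundant genes. A small share of cap cells is not excluded: 83 of the 510 genes were called higher in protoplasts than in intact tips, beside 2370 of all 25555, and the 257 abundant ones had a median of 0.40 in protoplasts minus intact tips. The 2 comparisons share intact tips: their changes had a covariance of 2.97 against 0.522 in simulated unchanged groups, and a correlation of 0.51 against 0.50, with 1870 genes higher in both (435 for independent lists), and part of the excess may come from the shared tips. The simulation held no true changes and the same spread per gene in all groups, and independent lists leave out the shared tips. Neither gives the overlap that shared tips alone would produce. The 2192 genes lower in protoplasts than in intact tips had a median of 1.60 in root cap minus protoplasts and of 2.92 in intact tips minus protoplasts. For these genes the cap was not at the level of the protoplasts. A common response to handling or wounding, or low levels particular to the intact tips, stays open and was not tested.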
